A study of Caulobacter vibrioides with 3 samples.

How the data were processed

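Occupancy of CtrA, the response regulator that controls much of the Caulobacter cell cycle, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3 strains of Caulobacter crescentus (also named Caulobacter vibrioides) NA1000. Per the labels' protocols, cells were grown in the complex medium PYE at 30 °C to mid-exponential phase and fixed with 1% formaldehyde. DNA was sheared to 300 to 500 bp and precipitated with a polyclonal antiserum against CtrA. The strains were wild type (WT), a mutant lacking divJ and pleC (the ΔdivJ ΔpleC mutant) and a mutant lacking divJ, pleC and cckN (the ΔdivJ ΔpleC ΔcckN mutant). Each strain had 1 library, so no replicate error could be computed and no test between genotypes was possible; every difference given is a difference between 3 libraries.

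Per the submitters' processing notes, BWA and MACS2 were used; their versions, settings and roles, an input control and the genome build are not given in the sources used here. The authors deposited 1 peak list per library, with no pooling of libraries. Each list gives the start, end and summit position of a peak, its height, an area, a normalised area and the genes and operons on either side. The height and the area are signal (coverage) values made by the authors on each library's own scale. The area is headed as reads in the deposited lists, but in the narrowest peaks (1 in WT, 4 in the ΔdivJ ΔpleC mutant and 1 in the ΔdivJ ΔpleC ΔcckN mutant) it equalled the height multiplied by the width minus 180 bp, so it was read as coverage summed over bases and not as a number of reads. The normalised area that the authors deposited is a fraction, the area divided by 1 constant per library, which exceeded the summed area of the listed peaks by 230 in WT, 314 in the ΔdivJ ΔpleC mutant and 193 in the ΔdivJ ΔpleC ΔcckN mutant. In WT, 9 of these deposited values were above 1 and looked as if they had lost a negative exponent. The fraction was therefore recomputed from the area and the constant in all 3 libraries and is given as a percentage, called the share of the summed peak signal. The deposited lists hold no fold enrichment and no significance value, so peak height took the place of both wherever the plan made before the data were examined had called for them.

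The sequencing depth is unknown, because no read totals are given, and so no counting interval is attached to a height or a share. The smallest listed height was 7 in WT and 8 in both mutants. Why a peak was left out of a list is not known, and its absence does not show that CtrA was absent. Coordinates are those of the deposited lists. Gene symbols came from the files and from a RefSeq gene table of NA1000 (assembly ASM2200v1, 4097 genes), matched on locus tag, which held 724 of 756 flanking genes in WT, 723 of 752 in the ΔdivJ ΔpleC mutant and 704 of 732 in the ΔdivJ ΔpleC ΔcckN mutant. No coordinate of that table is printed. Where both flanking genes were in the table, the summit lay between them in 348 of 350, 348 of 351 and 337 of 341 peaks. The peak that spans the origin of the coordinates carried genes from the middle of the chromosome in the lists and was reassigned to the last and first genes of the table, hemE and ccnA.

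Peaks of 2 lists were counted as shared when they overlapped by at least 1 bp. Shares of overlapped peaks carry exact 95% binomial (Clopper-Pearson) intervals. These treat the listed peaks as independent draws and leave out error in read counts and differences between replicate libraries. Each share stands beside the same share after 1000 seeded circular shifts of the second list. Peaks of the 3 lists that overlapped by at least 1 bp were merged into regions, and each region was assigned to 1 of the 7 combinations of libraries. Genes of 5 functional lists, of a control list of ribosomal protein and rRNA genes and of the 3 deleted loci, all fixed before the data were examined, were counted as having a peak when they flanked one. The count was set against 10000 random gene lists of the same size. The plan had been to count summits near annotated gene starts; without strand, this was replaced by the deposited flanking genes. A gene inside an operon without a peak of its own counts as having none. The search for the CtrA motif and the placement of summits inside or between genes were not run, since no genome sequence was used here.

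The sizes of peaks were compared between libraries only by a rule added after the data were examined, on 157 regions that all 3 lists hold and whose mean height was at least 20. A region was called higher or lower when both its share and its height, divided by the median height ratio of the 157 regions, differed by at least 1.5-fold in the same direction. The share is the comparison that the authors' own normalisation allows; it depends on what else was listed in a library. The 157 regions held 83.6% of the summed signal in WT, 86.5% in the ΔdivJ ΔpleC mutant and 81.9% in the ΔdivJ ΔpleC ΔcckN mutant, over 105322, 103417 and 98253 bp outside the region that spans the origin. Before centring, the median log2 height ratio was 0.58 for the ΔdivJ ΔpleC mutant over WT, 0.00 for the ΔdivJ ΔpleC ΔcckN mutant over WT and -0.60 for the second mutant over the first. Uncentred heights can thus give other directions in the comparisons that involve the ΔdivJ ΔpleC mutant. To see what counting alone gives, heights were redrawn 1000 times as Poisson counts with no difference between libraries, which takes a height as a number of overlapping reads. Medians of gene lists were set against 10000 random sets of the same size, matched on mean height in 4 bins, as a description of these libraries.

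The height criterion of the rule was tested alone, on heights simulated from the WT library for the ΔdivJ ΔpleC ΔcckN mutant over WT. With 30 of 147 simulated regions changed 2-fold in 200 draws, 90.2% of the changed regions were recovered and 8.92% of the unchanged ones were called. No share was simulated, and the simulated regions were not the same set as the compared ones. These rates thus do not give the recovery or false calls of the full rule. Named genes were chosen by a rule fixed beforehand: genes of the lists that flank a peak in at least 1 library, and up to 5 regions per combination with the greatest height. Regions named because they met the size rule were chosen after their values were seen. Alternatives covered the overlap required, the height threshold, lists of equal length, the merging distance, operon members, the measure of size, the minimum height, the tallest region, the region of the deleted loci and a trend with height, as a straight line and by medians of 3 height bins. Unchanged mutants for the flagellar list were simulated in the same way as above. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.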

Results

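CtrA occupancy was profiled by ChIP-seq in exponentially growing NA1000 cells of 3 genotypes, with 1 library each: WT, ΔdivJ ΔpleC and ΔdivJ ΔpleC ΔcckN. DivJ is a histidine kinase that phosphorylates the response regulator DivK, PleC acts mainly as a phosphatase of DivK, and the study asks about phosphatases with overlapping roles in cell cycle control. The lists held 378 peaks in WT, 376 in the ΔdivJ ΔpleC mutant and 366 in the ΔdivJ ΔpleC ΔcckN mutant, covering 202020, 195024 and 192744 bp. Peak heights ran from 7 to 1109 in WT (median 14), from 8 to 1738 in the ΔdivJ ΔpleC mutant (median 19) and from 8 to 1248 in the ΔdivJ ΔpleC ΔcckN mutant (median 15). Because WT was listed from a lower height, the same minimum of 8 in every list left 326 peaks in WT and all peaks of both mutants. Sequencing depth is unknown and there were no replicates, so no difference below could be set against replicate error.

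The same sites carried most of the CtrA signal in every genotype. The tallest peak lay at 1230835 to 1232027, between CCNA_01126 and CCNA_01127, which both encode hypothetical proteins, and held 9.74% of the summed peak signal in WT, 11.3% in the ΔdivJ ΔpleC mutant and 11.6% in the ΔdivJ ΔpleC ΔcckN mutant. It was followed by the regions between CCNA_03426 and CCNA_03427 (3591976 to 3592962; WT height 347) and between CCNA_03324 and CCNA_03325 (3505575 to 3507022; WT height 340). The region across the origin of the coordinates, between hemE and ccnA, had heights of 272, 383 and 236 in WT, the ΔdivJ ΔpleC mutant and the ΔdivJ ΔpleC ΔcckN mutant, and shares of 3.65%, 3.66% and 3.37%. The replication origin that CtrA is known to bind lies there. The region between CCNA_01529 and the flagellin gene fljJ (1637266 to 1638179) had heights of 267, 350 and 212. The 10 peaks with the greatest shares held 30.1%, 31.0% and 28.7% of the signal.

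Merging the lists gave 417 regions, of which 321 were listed in all 3 libraries. A further 27 were listed in WT and the ΔdivJ ΔpleC mutant, 14 in both mutants, 2 in WT and the ΔdivJ ΔpleC ΔcckN mutant, 20 in WT alone, 5 in the ΔdivJ ΔpleC mutant alone and 28 in the ΔdivJ ΔpleC ΔcckN mutant alone. No region missing from at least 1 list was taller than 23, and those listed in the mutants but not in WT reached at most 9, next to the smallest heights listed.

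**Figure D1:**
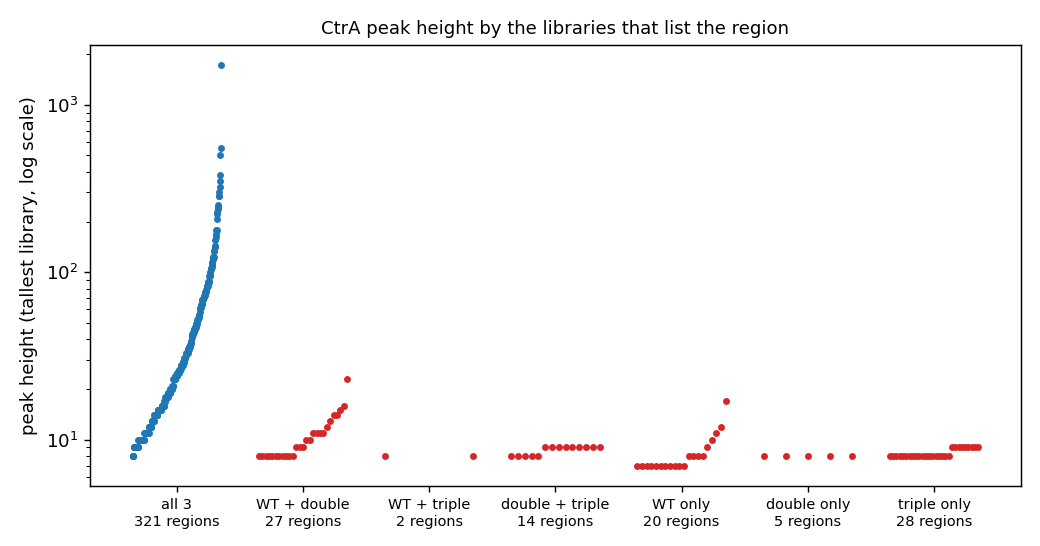
Each point is 1 merged CtrA region, placed by the combination of libraries that list it (double, ΔdivJ ΔpleC; triple, ΔdivJ ΔpleC ΔcckN) and by its greatest peak height in any of them (vertical axis, log scale, coverage units of each library). The 321 regions listed in all 3 libraries reach 1738, whereas regions missing from at least 1 list stay at 23 or below.

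The deleted loci gave a weak check of the labels. A peak beside pleC (2718318 to 2718689) was listed in WT, at a height of 9, and in neither mutant, but this height was close to the smallest listed. The peak between cckN and divJ, which are neighbours (1220092 to 1220605), had heights of 20, 35 and 13 in WT, the ΔdivJ ΔpleC mutant and the ΔdivJ ΔpleC ΔcckN mutant. Its share was 0.141%, 0.162% and 0.0675%, so the log2 ratio to WT was 0.20 with divJ and pleC deleted and -1.06 with cckN deleted as well (0.23 and -0.62 by centred height). Which bases each deletion removed is not given in the sources used here, so the values of this region are not read as a change in binding.

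In the mutant lacking DivJ and PleC most WT sites were listed again, and a few regions differed in size. The region beside divK (2696054 to 2696678), the gene of the response regulator that DivJ and PleC act on, held 0.235% of the signal in WT and 0.418% in the ΔdivJ ΔpleC mutant (log2 ratio 0.83). Beside the division gene ftsQ (2775500 to 2776132) the share was 0.322% in WT and 0.522% in the mutant (log2 ratio 0.70), and between fzlA, which encodes an FtsZ-binding protein, and rfaE (3924038 to 3924702) it was 0.403% and 0.688% (0.77). On the lower side were the region beside hvyA (178793 to 179535), an inhibitor of capsule formation in swarmer cells, with 0.452% in WT and 0.224% in the mutant (-1.01), and the region between the hook gene flgE and sciP (1025998 to 1027132), with 0.534% and 0.345% (-0.63). SciP is a repressor that acts in swarmer cells.

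Of the 378 WT peaks, 356 were overlapped by a peak of the ΔdivJ ΔpleC mutant (94.2%, exact 95% interval 91.3 to 96.3), against a mean of 9.49% after circular shifts. The 22 others had a median height of 7 and held 0.850% of the WT signal. The tallest of them lay between mreB and mreC (1733727 to 1734418; height 17), genes that maintain rod shape, and was listed in WT alone, as were the regions between CCNA_03923 and CCNA_00541 (height 12), CCNA_02544 and CCNA_02545 (11), and beside glnK (10). Among the 157 compared regions, 8 were higher and 7 lower in the ΔdivJ ΔpleC mutant by 1.5-fold in both measures. Besides those named, the higher ones were the regions beside crbA, between spmY and glpK, between CCNA_02342 and CCNA_02343, between CCNA_02534 and the topoisomerase I gene CCNA_02535, and between CCNA_01156 and CCNA_01157. The lower ones included the flagellin gene fljN and a chemoreceptor gene, CCNA_02901. By height alone 17 regions differed. Simulated counting error gave a mean of 12.0 such regions, with a central 95% range reaching 18, so the number lay inside that range. Between the mutants the same simulation gave a mean of 11.8 where 5 were seen. It may thus overstate counting error and cannot show that counting explains these regions. With a minimum mean height of 30, 4 higher and 3 lower regions met the rule, and 5 higher and 6 lower after the median of each of 3 height bins was removed.

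With cckN deleted as well, shares spread farther from WT: the SD of the log2 ratio across the 157 regions was 0.55, against 0.37 in the ΔdivJ ΔpleC mutant. By centred height the SDs were 0.51 and 0.37. Simulated counting error alone also gave more calls in this comparison, so part of the wider spread may come from counting. The share beside ftsQ was 0.649% against 0.322% in WT (log2 ratio 1.01), that between fzlA and rfaE 0.783% against 0.403% (0.96), and that beside ftsW (2787211 to 2787756) 0.258% against 0.168% (0.62). The region beside dgcA (3566019 to 3566770), which encodes a diguanylate cyclase, held 1.05% against 0.551% (0.92), and the region beside the holdfast inhibitor gene hfiA (938451 to 939300) held 1.20% against 0.669% (0.85). Lower shares were found beside hvyA, with 0.177% against 0.452% (-1.35), and between flgE and sciP, with 0.262% against 0.534% (-1.02). The flgE and sciP region held 2 peaks in the ΔdivJ ΔpleC ΔcckN library in place of 1, both of height 18 against 46 in WT. The region between CCNA_02060 and CCNA_02061 (2210116 to 2210646) had heights of 31 in WT, 21 in the ΔdivJ ΔpleC mutant and 8, the smallest listed, in the ΔdivJ ΔpleC ΔcckN mutant. Its log2 ratio of the last to WT was -1.95 by centred height and -3.11 by share, a measure that shrinks faster than height in low, narrow peaks.

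Of the WT peaks, 331 of 378 were overlapped by a peak of the ΔdivJ ΔpleC ΔcckN mutant (87.6%, exact 95% interval 83.8 to 90.7; mean 9.29% after shifts). The 47 others had a median height of 8 and held 2.21% of the WT signal. The tallest was beside hfsJ (105996 to 106554), a gene linked to holdfast synthesis, with heights of 23 in WT and 15 in the ΔdivJ ΔpleC mutant and no listed peak in the ΔdivJ ΔpleC ΔcckN mutant. Other regions missing from the last list alone were those beside CCNA_01768 (heights 15 and 16), CCNA_01773 (15 and 14) and kidO (14 and 11). The region between CCNA_02981 and CCNA_02982 (14 and 9) was also missing from that list alone. The gene kidO, which encodes a division inhibitor, flanked a taller peak in every library. Its heights were 38 in WT, 62 in the ΔdivJ ΔpleC mutant and 33 in the ΔdivJ ΔpleC ΔcckN mutant. Conversely, a peak beside dnaA, the replication initiator gene, was listed in the ΔdivJ ΔpleC ΔcckN mutant alone (5261 to 5670), at a height of 9, the greatest in that group. Others of this height included the regions beside CCNA_R0045, CCNA_R0132, ccoS and CCNA_00797. Of the 157 compared regions, 16 were higher and 13 lower than in WT, or 12 lower without the region of the deleted cckN and divJ. By height alone 34 regions differed, and the central 95% range from simulated counting error reached 24.

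Both mutants differed from WT in similar regions, though both were set against the same WT library. The size rule was met in both by 7 higher regions, against 0.815 for independent lists, and by 5 lower regions, against 0.580. No region was higher in one and lower in the other. Counted by height alone, 14 regions were shared, and unchanged mutants set against the same WT heights shared a mean of 4.43, with a central 95% range reaching 9. The independent value leaves out the shared library and the simulated one leaves out real effects, and 1 WT library cannot be split, so part of the excess may come from that shared library.

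**Figure D2:**
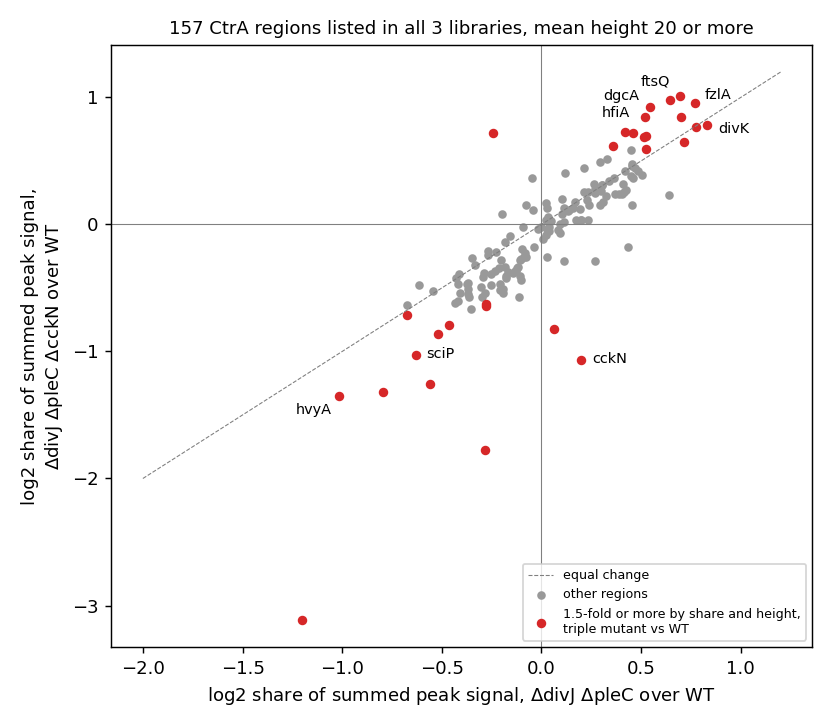
Each point is 1 of 157 CtrA regions listed in all 3 libraries; the axes give the log2 ratio of its share of the summed peak signal to WT in the ΔdivJ ΔpleC mutant (horizontal) and in the ΔdivJ ΔpleC ΔcckN mutant (vertical), and red marks the 29 regions that met the size rule in the latter, the triple mutant. The regions of ftsQ, fzlA, dgcA and hfiA lie above the dashed line of equal change, hvyA and sciP below it, and the region of cckN, which adjoins deleted loci, stands apart at 0.20 and -1.06.

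Few regions differed between the libraries of the mutants, which differ in the loss of cckN. Only 1 region was higher in the ΔdivJ ΔpleC ΔcckN mutant, that between qor and rho, the gene of a transcription termination factor (4038058 to 4038575), with 0.100% and 0.195% of the signal (log2 ratio 0.96). The 4 lower ones were between CCNA_02060 and CCNA_02061 (heights 21 and 8), between serS and CCNA_02079 (2229848 to 2230381; heights 31 and 11), at the deleted cckN and divJ (heights 35 and 13), and between CCNA_01185 and CCNA_01186 (1304356 to 1304923; heights 54 and 20). Their log2 ratios by centred height were -0.79, -0.89, -0.83 and -0.83; by share, which low peaks lose faster, they were -1.91, -1.49, -1.26 and -0.88. Of 376 peaks of the ΔdivJ ΔpleC mutant, 344 were overlapped in the other mutant (91.5%, exact 95% interval 88.2 to 94.1; mean 9.05% after shifts), and the 32 others had a median height of 8. By height alone the same number of regions, 5, differed, fewer than the mean of 11.8 from simulated counting error. The simulation may thus overstate counting error, and it detected no difference in number between the mutants. Without the region of the deleted genes 3 were lower. At a minimum mean height of 30 no higher region and 1 lower region met the rule.

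Genes of the CtrA regulon lists flanked peaks in every genotype far more often than random genes did. The lists were drawn up around genes that CtrA is known to control, so an excess was foreseen. Neighbouring listed genes, such as fliL and flgF, can share the same peak and were each counted. The random lists were drawn gene by gene, without such neighbours. Of 9 cell cycle regulators, 7 flanked a peak in WT, 7 in the ΔdivJ ΔpleC mutant and 8 in the ΔdivJ ΔpleC ΔcckN mutant, against a random mean of 1.48 in WT. The ctrA gene itself (3279305 to 3280112) had heights of 100, 162 and 118 and shares of 0.767%, 0.823% and 0.880% in WT, the ΔdivJ ΔpleC mutant and the ΔdivJ ΔpleC ΔcckN mutant. The methyltransferase gene ccrM had shares of 0.639%, 0.700% and 0.687%. For tacA, a regulator of stalk formation whose mean height fell short of the compared set, the values were 0.198%, 0.130% and 0.0855%. Smaller peaks flanked gcrA (heights 13, 14 and 11), mucR1 (11, 16 and 16) and mucR2 (29, 33 and 21), and staR flanked none.

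In the list of DivK and CckA phosphorylation, proteolysis and c-di-GMP genes, 12 of 17 flanked a peak in WT and 11 in each mutant (random mean 2.76 in WT). The mutant counts include deleted genes, through the peak between cckN and divJ: divJ in both mutants and cckN in the ΔdivJ ΔpleC ΔcckN mutant. Of its 8 compared regions, that of divK was higher in both mutants, the cckN and divJ region was lower in the ΔdivJ ΔpleC ΔcckN mutant, and the others stayed within the size rule against WT. Shares in WT, the ΔdivJ ΔpleC mutant and the ΔdivJ ΔpleC ΔcckN mutant were 0.159%, 0.172% and 0.161% for the phosphotransferase gene chpT, 0.312%, 0.358% and 0.320% for the phosphodiesterase gene pdeA, and 0.460%, 0.366% and 0.370% for rcdA, whose product aids CtrA degradation. Peaks of cpdR, dgcB, podJ, perP and shkA were also listed in all 3 libraries, whereas cckA, divL, pleD, popA and spmX flanked none.

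Of 16 division and chromosome segregation genes, 11, 10 and 11 flanked a peak in the same order (random mean 2.65 in WT). Among 8 compared regions, ftsQ was higher in both mutants and ftsW in the ΔdivJ ΔpleC ΔcckN mutant, with log2 ratios to WT of 0.36 and 0.62 in the 2 mutants. Values that did not meet it were 0.12 and 0.40 for ftsA, 0.33 and 0.51 for ftsK, -0.13 and -0.37 for mipZ, which positions the division plane, and -0.37 and -0.57 for ftsB. Between the mutants, the list's median log2 ratio was 0.03 by share and 0.16 by centred height, at percentiles 97.1 and 98.2 of random sets, and no member met the rule. The small peak of parB had a height of 7 in WT and 8 in the ΔdivJ ΔpleC ΔcckN mutant and was not listed in the ΔdivJ ΔpleC mutant; parA, kidO, dipM and hemE flanked peaks in all 3.

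Of 48 listed flagellum and chemotaxis genes, 40 were matched by symbol. Of these, 22, 22 and 21 flanked a peak (random mean 6.56 in WT). In both mutants, 11 of 14 compared regions had a lower share than WT. The number by centred height was also 11, against a mean of 4.71 for unchanged mutants set against the same simulated WT heights (central 95% range reaching 8). Matched random sets gave a mean of 6.95 (reaching 10). Part of the excess may come from the shared WT library. The median log2 ratio was -0.19 in the ΔdivJ ΔpleC mutant and -0.40 in the ΔdivJ ΔpleC ΔcckN mutant, at percentiles 1.56 and 1.66 of random sets, and -0.27 and -0.38 by centred height. Between the mutants it was -0.15 by share, at percentile 21.2. These percentiles were among 30 computed for the lists without correction. Shares were 1.93%, 1.79% and 1.45% beside flbT, 2.00%, 1.84% and 1.59% beside fljJ, 1.46%, 1.34% and 1.15% beside fliQ, and 0.791%, 0.684% and 0.622% between fliL and flgF. None of these 4 regions met the size rule. Of the 14, 2 did in the ΔdivJ ΔpleC mutant, fljN and the flgE and sciP region, both lower, and 1 in the ΔdivJ ΔpleC ΔcckN mutant, the flgE and sciP region. The 3 exceptions among the 14, with higher shares in both mutants, were the regions of motA (log2 ratios 0.45 and 0.46), motB (0.31 and 0.31) and fliI with fliJ. The genes motA and motB encode the flagellar stator. Left out of the 14 was the region of mcpA, a listed gene whose symbol was not matched. Its share was higher than WT in both mutants (log2 ratios 0.31 and 0.31, or 0.47 and 0.54 by centred height). The other unmatched genes were not looked up. The fljK and fljL peak, of height 12 in WT and 12 in the ΔdivJ ΔpleC mutant, was not listed in the ΔdivJ ΔpleC ΔcckN mutant.

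Of 17 matched pilus, holdfast and stalk genes, 8, 8 and 7 flanked a peak (random mean 2.80 in WT). Of 4 compared regions only hfiA met the size rule, in the ΔdivJ ΔpleC ΔcckN mutant. The pilin gene pilA (3198147 to 3199242) had shares of 0.744%, 0.576% and 0.509%, with log2 ratios to WT of -0.37 and -0.55, while the neighbouring region of cpaA and cpaB had 0.399%, 0.406% and 0.410% and that of hfsA and hfsD 0.394%, 0.402% and 0.384%. The control list of 32 ribosomal protein and rRNA genes had 6, 7 and 7 members beside a peak, against random means of 5.26, 5.21 and 5.22. This total near the random means mixed unlike groups. The 6 in WT were all rRNA genes, and each mutant added only the ribosomal protein gene rpsM. Ribosomal protein genes entered the list by symbol, so those named by locus tag alone were left out. For example, CCNA_00530 and CCNA_00531, both annotated as ribosomal proteins, flanked a peak of height 7 in WT and 8 in each mutant. Many ribosomal protein genes of the list are also neighbours, unlike random genes, so the list is not a neutral control.

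**Figure D3:**
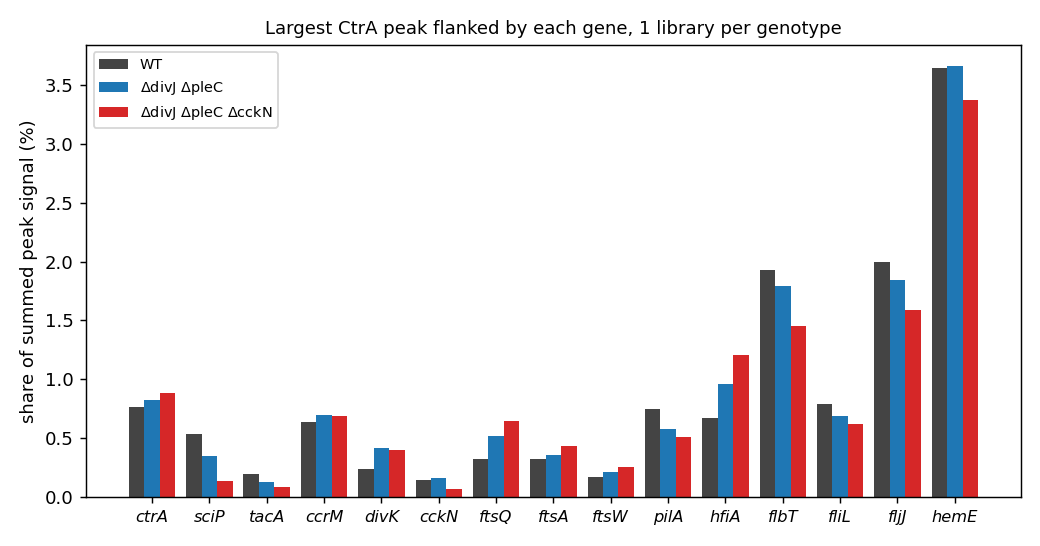
Bars give the share of the summed peak signal (vertical axis, percent) of the largest CtrA peak beside each gene, with 1 bar per library and no error bar because each genotype had 1 library. The bars of ftsQ and hfiA rise from WT to the ΔdivJ ΔpleC ΔcckN mutant (0.322% to 0.649% and 0.669% to 1.20%), and those of flbT and fljJ decline. For sciP the last bar is 1 of the 2 peaks of its region, the one with the larger share (0.140%).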

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

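The alternatives for peak size, the height threshold of 16 and the counting of operon members were chosen after the data were seen; the others were set before. No paired analysis was possible because each genotype had 1 library and no test was run. Overlap between lists depended mostly on low peaks. Keeping only peaks of the first list at or above its median height gave 99.5% for WT peaks in the ΔdivJ ΔpleC mutant, 97.0% for WT peaks in the ΔdivJ ΔpleC ΔcckN mutant and 100% for ΔdivJ ΔpleC peaks in the ΔdivJ ΔpleC ΔcckN mutant, and a minimum height of 16 in the first list gave 99.4%, 98.9% and 99.5%, because fewer low peaks were counted. Requiring summits within 100 bp gave 82.8% for WT in the ΔdivJ ΔpleC ΔcckN mutant and 87.8% between the mutants, and an overlap of 50% of both peaks gave 88.0% between the mutants; the cause was not tested. The other 9 overlap values stayed inside the interval of the reported one. With each list restricted to heights at or above its median, the regions in all 3 libraries numbered 170, those in WT and the ΔdivJ ΔpleC mutant 10, in WT and the ΔdivJ ΔpleC ΔcckN mutant 0, in both mutants 6 and in the ΔdivJ ΔpleC ΔcckN mutant alone 7, since fewer peaks entered, while regions in WT alone and in the ΔdivJ ΔpleC mutant alone stayed within 1.5 times; lists of equal length and merging up to 100 bp apart kept all 7 counts within 1.5 times. Counts of peaks and of listed genes also stayed within 1.5 times under every alternative run. A minimum mean height of 30 left 4 higher and 3 lower regions for the ΔdivJ ΔpleC mutant over WT, and 0 higher and 1 lower for the ΔdivJ ΔpleC ΔcckN mutant over the ΔdivJ ΔpleC mutant, with fewer regions compared; a minimum of 15 gave 2 higher in the latter, with more compared. Removing the median of each of 3 height bins left 5 higher for the ΔdivJ ΔpleC mutant over WT; the cause was not tested. The counts for the ΔdivJ ΔpleC ΔcckN mutant over WT stayed within 1.5 times under all 8 alternatives, from 13 to 18 higher and from 9 to 17 lower. Alternatives that needed gene starts, a motif or the placement of summits were not run. With depth unknown and 1 library per genotype, a peak near the smallest listed height cannot be called gained or lost.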

Other observations

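Peaks beside chemoreceptor genes were looked at after the lists were seen, and whether they are more frequent than beside other genes was not tested. Of 19 regions flanked by a gene annotated as a methyl-accepting chemotaxis protein, 18 were listed in all 3 libraries, and their shares moved both ways. Of the 10 large enough to compare, none was higher by the size rule in either mutant, 1 was lower in the ΔdivJ ΔpleC mutant and 2 were lower in the ΔdivJ ΔpleC ΔcckN mutant, those of CCNA_02901 (0.433%, 0.271% and 0.264% in WT, the ΔdivJ ΔpleC mutant and the ΔdivJ ΔpleC ΔcckN mutant) and CCNA_02402 (0.693%, 0.571% and 0.444%). The region of mcpA (CCNA_00439), the receptor gene of the main chemotaxis operon, had 0.815%, 1.01% and 1.01%. This gene was on the flagellum and chemotaxis list but did not enter its counts, because its symbol was not matched.

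The dgcA gene lay between a pair of peaks whose shares went opposite ways. On the side of CCNA_03395 the share was 0.551%, 0.805% and 1.05%, and on the side of CCNA_03393 (3565174 to 3565834) it was 0.298%, 0.242% and 0.201%, with log2 ratios to WT of -0.30 and -0.57. Broad low peaks covered both rRNA operons: beside the 23S genes CCNA_R0066 and CCNA_R0084 the shares were 0.565% and 0.577% in WT, 0.526% and 0.552% in the ΔdivJ ΔpleC mutant and 1.16% and 1.16% in the ΔdivJ ΔpleC ΔcckN mutant, where each was listed as 1 peak in place of 2. Greatest heights in the same order of libraries were 10, 12 and 14 beside CCNA_R0066 and 10, 13 and 14 beside CCNA_R0084. From WT to the ΔdivJ ΔpleC ΔcckN mutant the height thus rose less than the share, which also depends on the width listed. The operon copies are close to identical, so reads cannot be assigned to one of them with certainty.

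Of the tests below, those on the calling limit, on counting error and on a trend with peak height were chosen after the result was seen. Of the 42 regions listed in the ΔdivJ ΔpleC ΔcckN mutant but not in WT, 11 were next to tRNA, rRNA or ribosomal protein genes, against 2 of 47 listed in WT but not in that mutant and 9 of 321 listed in all 3 libraries. The 11 were 7 of 28 regions of that mutant alone and 4 of 14 listed in both mutants, so the pattern was not particular to the ΔdivJ ΔpleC ΔcckN library. The greatest height among those 42 regions was 9, where the list began at 8, so peaks close to the calling limit remain an explanation for their listing. This height cannot say why many lay beside such genes. The WT peaks not overlapped in that mutant were also low, with a median height of 8. A higher general signal over highly transcribed genes in that library also remains: in the 9 regions next to such genes that all 3 libraries list, the median log2 centred height ratio to WT was 0.37, above the central range of matched random sets (-0.25 to 0.35). The margin was narrow, and the 9 include regions of both rRNA operons, whose copies had near-equal heights. Such copies are not independent, whereas random sets were drawn region by region, so the margin may rest on them. In the ΔdivJ ΔpleC mutant the same 9 regions had a median of -0.05, inside the central range of matched random sets (-0.21 to 0.13). These values show no higher signal over such genes in that library, which also lists the 4 regions, beyond its general scale. Centring removes that scale. Before centring, the median height ratio of that library to WT over the 157 compared regions was 1.49. The centred values thus cannot say whether this scale brought the 4 regions into its list. What accounts for those 4 stays open, and a change in CtrA binding with genotype stays open and untested.

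If counting error in low regions caused the size differences between the ΔdivJ ΔpleC ΔcckN mutant and WT, few of the 29 regions would be among the taller ones, yet 44.8% lay at or above the median mean height (exact 95% interval 26.4 to 64.3, against a bound of 25%), which argues by a narrow margin against it as the whole cause and leaves single low regions open. A difference in DNA copy number along the chromosome would follow the distance from the origin; 27 of the 29 kept their call after that trend was removed (slope -0.08 log2 units of share per Mb). For a trend of the ratio with peak height, 24 of the 29 kept their call after the median of each of 3 height bins was removed, which argues against it as the cause of most of them. Still open are differences between single immunoprecipitations, which 1 library per genotype cannot separate from genotype, the genotype itself, which was not tested, and, for the region of the deleted cckN and divJ among the 29, missing DNA.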
